A study of Naumovozyma castellii with 6 samples.

How the data were processed

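Ribosome profiling, which sequences the RNA fragments that ribosomes protect from nuclease, was done in the budding yeast Naumovozyma castellii. The series holds 6 libraries, 3 of a wild-type strain and 3 of a strain whose UPF1 gene was replaced by a drug-resistance cassette. Upf1 is a helicase of nonsense-mediated mRNA decay, the pathway that degrades transcripts whose translation ends early. Per the labels' protocols, cells were grown in rich medium at 25 °C to an optical density of 0.5 and exposed for 15 min to cycloheximide, which blocks elongating ribosomes. Footprints were prepared from 20 absorbance units of extract, depleted of ribosomal RNA, end-repaired and made into small RNA libraries. These libraries carry no molecular identifiers as far as the labels say, so reads are not independent molecules. The intervals below cover counting error or the drawing of ORFs or XUTs. None covers variation between libraries.

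Per the submitters' processing notes, reads were trimmed with Trim Galore and aligned with HISAT2. The versions, the genome build, the read-length filter, the P-site offsets and the program that scored the ORFs are not given in the sources used here. The authors deposited a single merged table of 8742 open reading frames (ORFs) in 1002 Xrn1-sensitive unstable transcripts (XUTs), cytoplasmic long noncoding RNAs that are degraded by the 5′-to-3′ exonuclease Xrn1. Each ORF has 1 value per measurement. No column names a library or a strain, so no value could be assigned to wild type or to the upf1 mutant, and which of the 6 libraries were merged is not stated. The differential test and the phase-score shift planned for upf1 against wild type were therefore not run, and the effect of UPF1 was not analysed here. For the same reason there is no replicate error, and the depth of each library is unknown. The table sums to 212510 reads over the ORFs, which is not a library depth, because the table covers ORFs of XUTs alone and reads of overlapping ORFs enter more than once.

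The deposited read count of an ORF is a whole number that was not normalized. The deposited read density was tested against the other columns and is a coverage of reads per codon (read count divided by length in units of 3 nt) in every row. The deposited fraction of valid codons equals the number of valid codons over all codons of the ORF in every row. The deposited phase score runs from 0 to 1 and measures how far the footprints repeat with the 3-nt step of a translating ribosome. What makes a codon valid is not given in the sources used here. It is not the presence of reads alone, since 73 of the 2715 ORFs with reads had no valid codon. The authors' call of an ORF as translating was tested against the columns: every called ORF had at least 5 valid codons and a score of at least 0.323, and every ORF with 5 or more valid codons that was not called scored 0.317 or less. Start and end are given as in the table, whose ends lie length minus 1 after the starts. Chromosome numbers are the table's own.

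From these columns, shares of ORFs were computed with Wilson 95% intervals in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3. The intervals describe the ORFs of this merged table, and ORFs are not biological replicates. They treat ORFs as independent, although calls cluster within XUTs and ORFs overlap, and so may be too narrow. Median lengths of called and other ORFs were compared by a two-sided permutation test with 100000 shuffles. That test was repeated within terciles of read count, set among ORFs with at least 5 reads because most ORFs had none. Classes were compared by two-sided permutation tests with 100000 shuffles. For strand and chromosome, whole XUTs were shuffled. For order and length, which vary within an XUT, the calls were shuffled within each XUT. The 4 class tests were adjusted by Benjamini and Hochberg's method at a threshold of 0.05. The smallest p-value these shuffles can give is 1e-05. Order counts from the 5′ end among the ORFs listed for an XUT, since the table holds no transcript ends. Where a setting keeps only part of the ORFs, order counts among those kept, in XUTs with at least 2 of them. Length terciles are then drawn anew as well. Start codons and XUT classes such as antisense are not columns of the table and were not analysed here. Correlations across ORFs are given as Spearman's rho with a 95% interval from 1000 draws of XUTs with replacement, and Pearson's r.

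The ORFs named in the text were fixed by rule before the data were examined. Among called ORFs with at least 100 reads, the rule takes the 10 with the highest phase score, the 10 with the most reads and the 10 longest. It adds the XUT with the most called ORFs. The main tests were also fixed then, but were not all run as planned. The plan shuffled labels between XUTs for every class, whereas calls were shuffled within XUTs for order and length. It set no minimum of reads for the read-count terciles. The ORFs of XUT0292, XUT0259, XUT0605, XUT0277, XUT0327 and XUT0092 and the 375-nt ORF of XUT0739 described below lie outside the naming rule and were chosen after the data were seen. The permutation tests were tested on simulated data in which calls were placed on the 8742 ORFs. Calls were placed on single ORFs, with fewer shuffles than in the main tests. The clustering of calls within XUTs is therefore not part of the simulation. With random placement, 0 of 20 simulated tables passed for length, order, length tercile and chromosome and 1 of 20 for strand. With a planted effect, 20 of 20 passed for each. The alternatives tried were other phase-score thresholds, minimum reads, lengths and valid codons, and 1 ORF per XUT. Others were added after the data were seen, such as keeping 1 ORF per overlap group. A gene table of the N. castellii assembly ASM23734v1 was used only to find the neighbouring genes of XUTs, since the build of the deposited coordinates is not given in the sources used here. An exact chance of each phase score was computed on the assumption that the score is the length of the mean of unit vectors, 1 per valid codon, each in 1 of 3 phases at random. Since not all scores fit 3 phases, the Rayleigh test, in which phases lie anywhere on a circle, was added after the data were seen (Zar's approximation). Both were adjusted over the 655 ORFs with at least 5 valid codons by Benjamini and Hochberg's method. Figures were drawn with matplotlib 3.10.9.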

Results

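Ribosome footprints were mapped to ORFs of XUTs in Naumovozyma castellii to find which of these unstable noncoding transcripts carry ribosomes that move in 3-nt steps. The series comprises 3 wild-type and 3 upf1 libraries, all from cycloheximide-treated cells. The merged table gives 1 value per ORF with no replicate error, so no difference between the strains could be measured. It lists 8742 ORFs in 1002 XUTs on 10 chromosomes, with a median of 7 ORFs per XUT (interquartile range 4 to 11) and up to 70. The ORFs were mostly short, with a median of 45 nt, quartiles of 27 and 84 nt and a range from 15 to 3393 nt. Reads were sparse: 6027 ORFs (68.9%, Wilson 95% interval 68.0 to 69.9%) had no read, and 248 XUTs had no read in any ORF.

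The first question was how many XUT ORFs bear periodic footprints. The authors' call marked 577 of the 8742 ORFs as translating (6.60%, Wilson 95% interval 6.10 to 7.14%). Called ORFs had a median of 40 reads (interquartile range 19 to 126), 9 valid codons (6 to 14), 1.70 reads per codon (0.526 to 5.18) and a phase score of 0.595 (0.485 to 0.717). The 2138 ORFs that had reads but were not called had a median of 2 reads and 1 valid codon. Most ORFs with enough valid codons were called: 655 ORFs reached 5 valid codons, and 577 of these (88.1%, interval 85.4 to 90.4%) also passed the score, leaving 78 that did not. Called ORFs held 197869 of the 212510 reads (93.1%, interval 93.0 to 93.2%). ORFs with fewer than 5 valid codons, mostly those with few reads, cannot be called. Reads of overlapping ORFs enter more than once, so intervals for shares of reads are too narrow, here and below. Of the called ORFs, 538 had at least 10 reads, 341 at least 30 and 171 at least 100. Small ORFs made up most of the calls, with 519 of 577 (89.9%, interval 87.2 to 92.1%) shorter than 300 nt and 336 shorter than 100 nt. Of the called ORFs, 327 had 5 to 9 valid codons. If each codon took 1 of 3 phases at random, the score would be passed by 63.0% of ORFs with 5 valid codons, 38.3% with 6 and 53.3% with 7 to 9, and with phases drawn on a full circle by 64.6%, 54.0% and 45.1%; the observed shares were 90.5%, 90.8% and 83.1%. Neither rule of random phases is known to be that of the score. The number of calls was 287 at a phase score of at least 0.6, and 374 without the XUTs that hold an ORF of 600 nt or more.

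**Figure D1:**
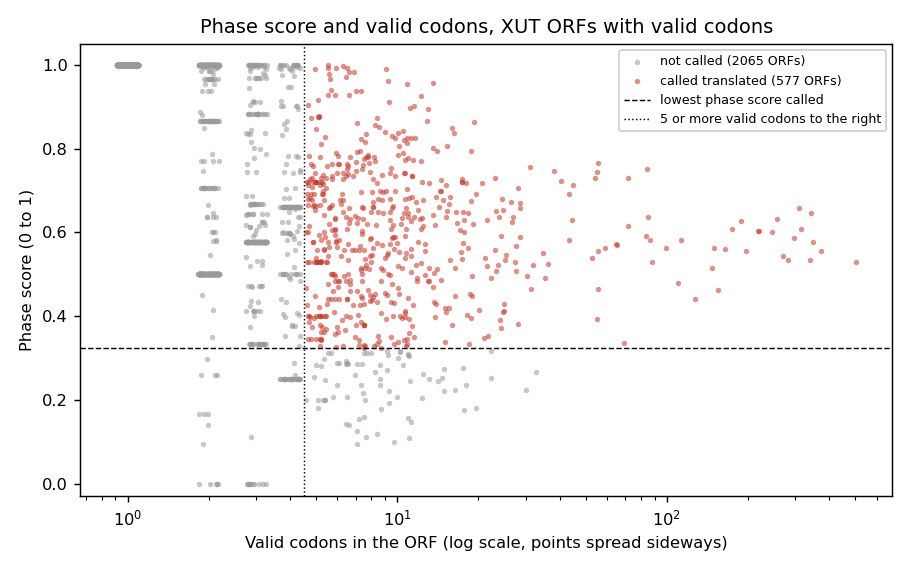
Phase score (vertical axis, 0 to 1) against the number of valid codons (horizontal axis, log scale, points spread sideways to separate them) for the 2642 XUT ORFs with at least 1 valid codon, each point 1 ORF of the merged table. The 2065 that were not called are grey, and 73 ORFs with reads but no valid codon are not drawn. The 577 called ORFs (red) fill the region at 5 or more valid codons and a score of at least 0.323, while ORFs with 1 valid codon all sit at a score of 1 without being called.

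Reads were concentrated in a few ORFs. The ORF with the most reads was a 237-nt ORF of XUT0250 on chromosome 1 (2909188 to 2909424, plus strand), with 35470 reads, or 16.7% of all reads in the table (Wilson 95% interval 16.5 to 16.9%). Of its 79 codons 78 were valid, at 449 reads per codon and a phase score of 0.751. The other 9 of the 10 ORFs with most reads were between 624 and 3393 nt long. The 1101-nt ORF of XUT0980 (chromosome 10, 66380 to 67480, minus strand) had 15167 reads, a score of 0.658 and 299 valid codons. The 783-nt ORF of XUT0802 (chromosome 7, 393656 to 394438, minus strand) had 12354 reads and a score of 0.627. The 1344-nt ORF of XUT0929 (chromosome 9, 83658 to 85001, minus strand) had 7518 reads and a score of 0.646, and the 624-nt ORF of XUT0870 (chromosome 8, 155266 to 155889, plus strand) had 6022 reads and a score of 0.563. These 10 ORFs together held 97418 reads (45.8%, interval 45.6 to 46.1%), and their scores ranged from 0.530 to 0.751. The remaining 5, in XUT0989, XUT0115, XUT0937, XUT1015 and XUT0915, had between 3286 and 5228 reads.

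Long ORFs were nearly all called. Of the 30 ORFs of 600 nt or more, 29 were called (96.7%, Wilson 95% interval 83.3 to 99.4%), each in a different XUT. They held 86564 reads (40.7% of the table, interval 40.5 to 40.9%). Of the 30 XUTs with such an ORF, 28 lay between genes of the assembly ASM23734v1 whose locus tags skip a number, against 36 of the 972 other XUTs (two-sided Fisher's exact test, p = 1.9e-34). The phase scores of the 29 lay between 0.410 and 0.658, with a median of 189 valid codons. The longest was a 3393-nt ORF of XUT0915 (chromosome 8, 667670 to 671062, plus strand), with 3286 reads, 497 of 1131 codons valid and a score of 0.530. The next were a 2688-nt ORF of XUT0454 (chromosome 3, 306685 to 309372, minus strand) with 2366 reads and a score of 0.555, and a 2319-nt ORF of XUT0641 (chromosome 5, 386327 to 388645, plus strand) with 1504 reads and a score of 0.602. The 10 longest called ORFs with at least 100 reads spanned 1545 to 3393 nt and 339 to 5228 reads. They lay in XUT0915, XUT0454, XUT0641, XUT0483, XUT0069, XUT0115, XUT0937, XUT0989, XUT0738 and XUT0563. The lowest score among them was 0.440, in XUT0738, and 4 of the 10 were also among the ORFs with most reads.

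The highest phase scores belonged to very short ORFs. Among called ORFs with at least 100 reads, the 10 highest scores ran from 0.848 to 0.993, in ORFs of 18 to 105 nt with 6 to 18 valid codons. Few valid codons alone favour high scores. If each codon took 1 of 3 phases at random, 38.3% of ORFs with 6 valid codons would pass the threshold, against 0.0633% with 50 or more. This ranking therefore does not show that short ORFs are more periodic than long ones. A 24-nt ORF of XUT0915 (668152 to 668175) had the highest score, 0.993, with 100 reads and 6 valid codons. A 21-nt ORF of XUT0448 (chromosome 3, 256647 to 256667, minus strand) scored 0.979 with 218 reads, and a 21-nt ORF of XUT0915 (667746 to 667766) scored 0.971 with 135 reads. The others lay in XUT1015, XUT0980, XUT0739, XUT0982 and XUT0965. Of these 10 ORFs, 8 lay wholly inside a longer called ORF of the same strand, and all overlapping ORFs in the table were in different reading frames. The 57-nt ORF of XUT0739, outside these 8, lay inside a 375-nt ORF that was not called (score 0.224), and overlapped a listed gene. None of the 10 was among those with most reads or the longest.

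Counted by transcript, 271 of the 1002 XUTs had at least 1 called ORF (27.0%, Wilson 95% interval 24.4 to 29.9%). That number was 126 when at least 10 valid codons were required and 129 and 116 under chance tests of the phase score (exact with 3 phases, and Rayleigh's). A single ORF was called in 159 XUTs, 2 ORFs in 56, 3 in 23 and 4 or more in 33. These 33 XUTs held 237 of the 577 calls (41.1%, interval 37.1 to 45.1%). The longest ORF of the XUT was among the called ones in 153 of the 271 XUTs (56.5%, interval 50.5 to 62.2%). XUT0915 had the most, with 22 of its 38 ORFs called, followed by XUT1015 with 15 of 18, XUT0454 with 13 of 22 and XUT0989 with 11 of 15. In each of these 4 XUTs the called ORFs formed 1 group of overlapping ORFs. Over the whole table the 577 calls fell into 322 groups that shared no nucleotide on a strand, and 233 called ORFs overlapped no other called ORF. Reads in a shared stretch enter the count of each ORF there.

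**Figure D2:**
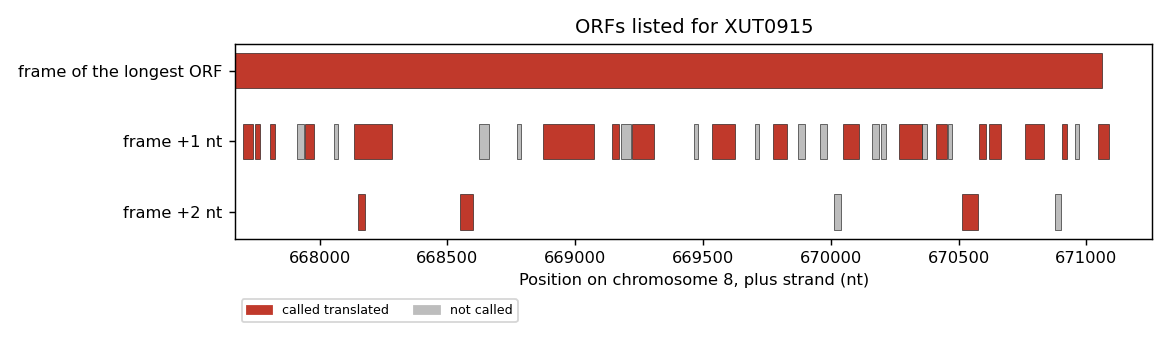
Map of the 38 ORFs listed for XUT0915 on chromosome 8, plus strand (horizontal axis, position in nt), drawn to scale in 3 reading frames relative to the longest ORF (rows). Called ORFs are red and the others grey; 21 of the 22 called ORFs are short ones that overlap the 3393-nt ORF in another frame.

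Called ORFs were longer than the rest. The median length was 87 nt (interquartile range 51 to 156) in the 577 called ORFs and 45 nt (27 to 78) in the 8165 others, a difference of 42 nt (two-sided permutation test with 100000 shuffles, p = 1e-05, the smallest they can give). This test, like those within read terciles, shuffles single ORFs, although calls cluster within XUTs. With calls shuffled within each XUT, a check added after the data were seen, p was 0.0005 (permutation test with 2000 shuffles). The difference was present within each tercile of read count. It was 57 nt at 5 to 10 reads (61 called ORFs against 373 others), 45 nt at 11 to 31 reads (187 against 177) and 39 nt at 32 or more reads (329 against 62), with adjusted permutation p-values of 1.5e-05, 1.5e-05 and 0.00126. Among ORFs with at least 100 reads it was 30 nt and did not pass the permutation test (p = 0.28). A call requires 5 valid codons, which is every codon of the shortest ORFs, of 15 nt. Among the 655 ORFs that reached 5, called ORFs were 18 nt shorter than the others, a difference that did not pass the permutation test (p = 0.0653).

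By length tercile, 63 of 3188 ORFs of up to 33 nt were called (1.98%, Wilson 95% interval 1.55 to 2.52%), 158 of 2683 of up to 66 nt (5.89%, 5.06 to 6.84%) and 356 of 2871 longer ones (12.4%, 11.2 to 13.7%). The longest tercile exceeded the shortest by 10.4 percentage points, against 1.02 for calls shuffled within each XUT (permutation test, p = 1e-05, adjusted p = 2e-05 over 4 class tests). Among the ORFs with at least 5 valid codons, with terciles drawn anew there, the difference was -7.55 percentage points and did not pass the permutation test (adjusted p = 0.558). The difference was 3.80 and 1.56 percentage points at phase scores of at least 0.6 and 0.7, where 287 and 154 ORFs were called. Among ORFs with at least 10 reads, of which 538 of 804 were called, it was 30.1. With at least 100 reads it was 8.59 and did not pass the permutation test. Terciles were drawn anew in these sets of reads too. Each test compares the difference with the mean of shuffles in its own set, which is given here for the full table alone. Since the share called differs between settings, the sizes of these differences are not comparable.

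ORFs near the 5′ end of an XUT were called more often than those further along. In the 954 XUTs with at least 2 listed ORFs, the first ORF was called in 129 (13.5%, Wilson 95% interval 11.5 to 15.8%), and 444 of the 7740 later ORFs were called (5.74%, 5.24 to 6.28%). The difference of 7.79 percentage points exceeded that of shuffles within each XUT, which averaged -0.107 (permutation test, p = 1e-05, adjusted p = 2e-05). In the XUTs with at least 5 ORFs, the share called was 15.7% at the first position, 12.1% at the second, 8.09% at the third, 6.62% at the fourth and 4.85% at the fifth, each over 680 ORFs. First ORFs also had reads more often (52.1% against 28.4%). Within the longest tercile, 25.4% of 350 first ORFs and 10.5% of 2507 later ORFs were called, and within the shortest 3.28% of 305 and 1.85% of 2860. At phase scores of at least 0.6 and 0.7, where 287 and 154 ORFs were called, the difference was 2.91 and 0.862 percentage points (adjusted permutation p = 2e-05 and 0.0343). Among ORFs with at least 10 reads, of which 538 of 804 were called, it was 0.676 (adjusted permutation p = 0.0407). It did not pass the permutation test among ORFs with at least 30 reads (3.48 percentage points, adjusted p = 0.137) and was -1.03 among those with at least 100 (adjusted permutation p = 0.78). Among the ORFs with at least 5 valid codons the difference was -0.866 percentage points and did not pass the permutation test (adjusted p = 0.238). In sets limited by reads or valid codons, the first ORF is the first one kept. Each test compares the difference with the mean of shuffles in its own set, which is given here for the full table alone. The share called also differs between settings, so these differences do not show whether the excess of first ORFs shrank.

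No difference by strand or chromosome passed the test. On the plus strand 291 of 4198 ORFs were called (6.93%, Wilson 95% interval 6.20 to 7.74%) and on the minus strand 286 of 4544 (6.29%, 5.62 to 7.04%), a difference of 0.638 percentage points (permutation test over XUTs, adjusted p = 0.565). Chromosome shares ran from 4.49% on chromosome 2 (59 of 1314 ORFs) to 10.8% on chromosome 9 (45 of 416), with 10.7% on chromosome 10 (58 of 544). The spread over the 10 chromosomes did not exceed that of shuffled XUTs (p = 0.139, adjusted p = 0.186, permutation test). It passed the permutation test at a stricter phase score of at least 0.6 (adjusted p = 0.0372).

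**Figure D3:**
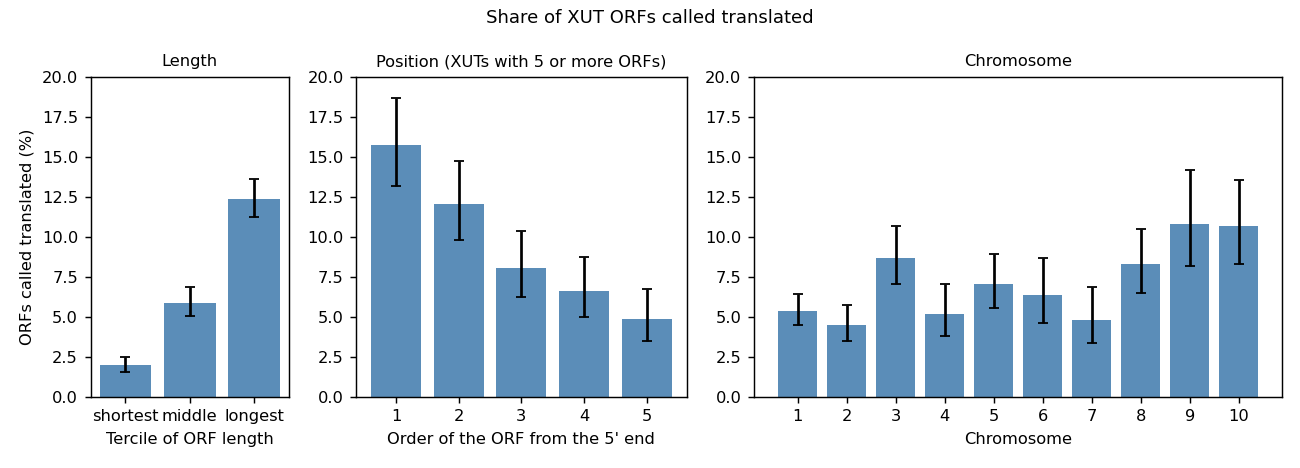
Share of XUT ORFs called translated (vertical axes, percent) by tercile of ORF length (left), by order of the ORF from the 5′ end in XUTs with at least 5 listed ORFs (middle) and by chromosome (right). Bars are shares of ORFs in the merged table. Error bars are Wilson 95% intervals, which treat ORFs as independent although calls cluster within XUTs. The share falls from 15.7% at the first position to 4.85% at the fifth.

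The phase score followed coverage in a way that depended on which ORFs were included. Across all 8742 ORFs, where ORFs are not independent replicates, Spearman's rho between phase score and read count was 0.92 (95% interval 0.91 to 0.93). The 6027 ORFs without reads have a score of 0 and so tie at the bottom of both rankings. Pearson's r was 0.053, and -0.042 across the ORFs with reads. Within the shortest, middle and longest length terciles rho was 0.95, 0.93 and 0.83. Across the 2715 ORFs with reads, rho was -0.59 (-0.62 to -0.56), and the 1141 ORFs with 1 valid codon all scored 1. Across ORFs with at least 10, 30 and 100 reads, the minima set before the data were seen, rho was -0.017, 0.00014 and -0.012. Across the 655 ORFs with at least 5 valid codons, a set chosen afterwards, it was 0.19 (0.11 to 0.27). Between phase score and length, rho was 0.21 (0.18 to 0.23) across all ORFs, -0.19 (-0.22 to -0.15) across those with reads and -0.26 (-0.34 to -0.17) across those with at least 5 valid codons.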

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

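No paired analysis was possible because the table holds merged values with no column for a library or strain; leaving out replicates was not possible for the same reason. Some settings were chosen after the data were seen: no minimum of valid codons, the exact chance test, the Rayleigh test, overlap groups, ORFs with at least 5 valid codons or 1 read, leaving out XUTs with an ORF of 600 nt or more, and the shuffle of lengths within XUTs. The shuffle within XUTs for the order and length classes and the minimum of 5 reads for the read-count terciles departed from the plan. The number of called ORFs, 577 as deposited, lay between 396 and 591 under 6 settings. It was 287 and 154 at phase scores of at least 0.6 and 0.7, 341 and 171 with at least 30 and 100 reads, 249 for the ORF of each XUT with most reads, 250 with at least 10 valid codons, 2512 with no minimum of valid codons, 277 under the exact chance test, 255 under the Rayleigh test, 314 for 1 ORF per overlap group, 322 for 1 called ORF per group of called ORFs and 374 without XUTs that hold an ORF of 600 nt or more. The number of XUTs, 271 as deposited, was 152 and 97 at scores of 0.6 and 0.7, 139 and 73 with at least 30 and 100 reads, 126 with at least 10 valid codons, 735 with no minimum, 129 under the exact chance test and 116 under the Rayleigh test. The length difference of 42 nt kept its direction and passed the permutation test under 14 settings (18 to 78 nt). It was 30 nt with at least 100 reads, no longer past the permutation test (p = 0.28), and -18 nt among ORFs with at least 5 valid codons. For the length terciles the difference was 3.80 and 1.56 percentage points at scores of 0.6 and 0.7 and 30.1 with at least 10 reads. It did not pass with at least 100 reads (8.59 percentage points) and was -7.55 with at least 5 valid codons. The difference between first and later ORFs, 7.79 percentage points, was 2.91 and 0.862 at scores of 0.6 and 0.7 (adjusted permutation p = 2e-05 and 0.0343) and 0.676 with at least 10 reads (0.0407). It did not pass with at least 30 reads (3.48 percentage points), and was -1.03 with at least 100 reads and -0.866 with at least 5 valid codons. Order and length terciles were set anew among the ORFs kept, and their tests compare with shuffles in each set. The share called also differs between settings, so these differences cannot be compared in size. The strand difference, never past the test, was -1.17 and -0.854 with at least 10 and 100 reads. The chromosome spread passed at a score of at least 0.6 alone (6.11 percentage points). The correlation of score with read count was -0.017, 0.00014 and -0.012 with at least 10, 30 and 100 reads, 0.35 for the ORF of each XUT with most reads, -0.59 with at least 1 read and 0.19 with at least 5 valid codons. That with length was -0.35, -0.34 and -0.32 with at least 10, 30 and 100 reads, -0.12 for the ORF of each XUT with most reads, -0.19 with at least 1 read and -0.26 with at least 5 valid codons. Settings that keep ORFs with reads remove the 6027 ORFs without reads, which have a score of 0; other causes were not tested. The order and length-tercile tests shuffle within XUTs and cannot be run with 1 ORF per XUT. A minimum of 5 valid codons is the deposited call itself. The depth of the libraries is unknown, and whether the 6027 ORFs without reads are translated was not detectable at this depth.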

Other observations

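All tests here are treated as chosen after the values were seen, except the count expected with random phases in 3 fixed positions. Outside the long ORFs, 215 called ORFs shorter than 300 nt, in 184 XUTs without an ORF of 600 nt or more, overlapped no other called ORF, and 62 of them passed the exact chance test described below (52 the Rayleigh test). Their median was 96 nt and 20 reads, and 22 had at least 100 reads. The one with most reads, named here after its values were seen, was a 231-nt ORF of XUT0292 (chromosome 2, 367422 to 367652, minus strand) with 2229 reads, 57 of 77 codons valid and a phase score of 0.766. A 204-nt ORF of XUT0259 (chromosome 2, 12826 to 13029, minus strand) had 995 reads and a score of 0.714, but lay at a skip of locus tag numbers (between NCAS0B00160 and MSC1), as most of the long ORFs below do. A 51-nt ORF of XUT0605 (chromosome 5, 6962 to 7012, plus strand) had 677 reads, 15 of 17 codons valid and a score of 0.713. Many reads did not always go with a high score: 11 ORFs with at least 100 reads and 5 or more valid codons were not called, with scores of at most 0.285. Another 8 with at least 100 reads had fewer than 5 valid codons. The ORF with most reads among the 11, 153 nt long in XUT0277 (chromosome 2, 164899 to 165051, plus strand), had 662 reads, 16 valid codons and a score of 0.223.

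The ORFs of 600 nt or more stood out when placed among the genes of the N. castellii assembly ASM23734v1. The build behind the deposited coordinates is not given in the sources used here. A common frame was tested by shifting the ORFs: 41.3% of their length lay in listed genes in place, 40.3% and 40.2% after shifts of 200 nt to either side, 57.2% and 57.5% after 1000 nt and 71.6% and 72.7% after 5000 nt, so the frames match to better than 1000 nt. In the 972 XUTs without an ORF of 600 nt or more, the longest ORF overlapped a listed gene in 489 (50.3%). It did so in 2 of the 30 XUTs with such an ORF. The gene table gives no strand, so whether these ORFs lie on the strand of the gene was not analysed here. A coding origin of reads in the shorter ORFs was therefore not excluded. Of the 30 XUTs with an ORF of 600 nt or more, 28 (93.3%, Wilson 95% interval 78.7 to 98.2%) lay where the numbering of locus tags, which runs in steps of 10, skips a number between the flanking genes, against 36 of 972 other XUTs (3.70%, 2.69 to 5.08%; two-sided Fisher's exact test, p = 1.9e-34). Only 57 of 5579 neighbouring gene pairs have such a skip, and moving the same ORFs by 20000 or 50000 nt to either side put at most 1 of 30 at a skip. These 28 long ORFs held 86456 reads; examples are XUT0929 beside RPP2A, XUT0870 beside RRP6, XUT0937 beside EXO84 and XUT0915 beside MAK11. A candidate explanation is that these XUTs span protein-coding genes or gene remnants that the gene table used here does not list, so that a sizeable part of the reads would not come from noncoding RNA. The gene table may itself be held here only in part, so whether a gene is annotated at these places was not analysed here. Length alone, at an equal read density, was tested as an explanation of their reads. Against all shorter called ORFs, which include those inside the long ones, their median reads per codon was 2.13 times as high (two-sided permutation test, p = 0.0807). Against the 374 called ORFs of XUTs without an ORF of 600 nt or more, which share no reads with them, it was 3.93 times as high (p = 0.0015, permutation test), and 4.53 times with 1 ORF per XUT (241 ORFs, permutation p = 0.00053), so equal density does not hold for typical ORFs. Summed over ORFs the difference is smaller: the long ones make up 40.8% of the length of called ORFs and 43.7% of their reads, and the ratio of pooled reads per codon to the 374 was 1.28 (95% interval 0.507 to 3.82 over draws of XUTs; 2.37 without the XUT0250 ORF), a spread too wide to decide. No biological explanation was tested, since the table separates no groups.

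Of the 577 called ORFs, 200 (34.7%) lay wholly inside 1 of 53 longer called ORFs, 161 of them inside one of 600 nt or more. None was in the frame of the outer ORF. The read densities of inner and outer ORFs went together (Spearman's rho 0.63 across the 200 pairs, which are not independent), which the level of the shared transcript would also give. Double counting was therefore tested on all 593 ORFs with reads that lie inside a longer ORF, called or not, 221 of them with up to 3 reads. None had more reads than the outer ORF (100% had as many or fewer, 74 exactly as many). For 166 of them (8 called), the XUT held an ORF within 1.5 times the outer length that did not overlap the inner one, and 96 of the 166 had more reads than the nearest such ORF (57.8%, Wilson 95% interval 50.2 to 65.1%). The inner ORFs were chosen for having reads and the control ORFs were not, which raises the 57.8%. Position along the XUT was not matched either. The control therefore cannot decide how often length or transcript level alone would leave an inner ORF with fewer reads. Reads counted in both ORFs would leave no inner ORF above its outer one, as was seen in all 593. The phase score of an inner ORF may then reflect the periodicity of the outer frame, as it does not say which frame the reads follow if it is the length of a mean phase vector. Whether some inner ORFs are translated in their own frame stays open, because the table gives no reads per frame.

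The threshold may also be passed by chance in ORFs with few valid codons. All 1141 ORFs with 1 valid codon scored 1, and 320 of 436 with 2 scored 0.5 or 1 (tolerance 1e-06), as the length of a mean of unit vectors in 3 phases would. The other 116 of the 436 had scores that 3 fixed phases cannot give (median over the 436, 0.707), so the assumption of 3 phases fails for these. Under it, codons with random phases would put 255 of the 655 ORFs with at least 5 valid codons past the threshold (exact, 95% range 233 to 277) and with phases drawn on a full circle 254, against 577 observed, so random phases alone, under either rule, do not account for the calls. With 1 ORF per overlap group the values were 140 expected (upper end 156) and 314 observed of 364. At 5 valid codons random phases would pass in 63.0% of ORFs, against 90.5% observed (105 of 116, Wilson 95% interval 83.8 to 94.6%), and at 20 to 49 in 6.36% against 92.5%. Singly, 277 called ORFs in 129 XUTs had an adjusted exact p under 0.05, among them 87 of the 327 with 5 to 9 valid codons and 190 of the 250 with 10 or more. The Rayleigh test, which does not assume 3 phases, kept 255 called ORFs in 116 XUTs (70 and 185 in these classes), 252 of them the same. In a simulation on the 655 ORFs, 200 were made periodic, with each codon in phase at a chance of 80%. This chance was not matched to the scores seen, with a median of 0.595 in called ORFs and 0.561 in those of 600 nt or more. Recovery at the periodicity seen is therefore not known. At this single setting 43.0% of the periodic ORFs were recovered with 1 false call. A call lost under the exact test is therefore at most weak evidence against translation.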
